A study of Homo sapiens with 9 samples.

How the data were processed

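Expression was measured by RNA sequencing in 9 libraries of Kasumi-1 cells, 3 each of a scramble control and of 2 knockdown groups, K2133 and K2231. Per the labels' protocols, the cells were grown in RPMI-1640 with fetal bovine serum, hairpins against F-CircAE were delivered by lentivirus in a pLKO.1 vector carrying puromycin resistance or GFP, RNA was treated with DNase I, and NEBNext Ultra libraries were read as paired ends on an Illumina HiSeq. The labels do not say which vector carried which hairpin. The deposited values of the authors are FPKM (fragments scaled to exon length and library depth), a unit inferred from the values, since no label or file header names it: the low values of a gene were whole multiples of a step that falls with exon length and with 1 depth per library. The genome build is hg38, per the submitters' processing notes, and the aligner, counter and annotation are not given in the sources used here. The tables list 29831 Ensembl genes. 8 libraries had a file of their own, whose values equalled the matching column of the table holding all 9.

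Gene symbols, biotypes and positions came from GENCODE release 29 (hg38), in which 29139 IDs (97.7%) were found. Depth was recovered from the FPKM steps and the exon lengths: with a tolerance of 0.02 reads, 92.5% of the genes with a length (26953) gave whole reads in all 9 libraries, and 93.8% of single values were whole. By group the depth in M reads was 15.7 ± 2.13 M reads in scramble, 16.9 ± 2.85 M in K2133 and 16.8 ± 1.95 M in K2231 (SD, n = 3). The number of reads limits the precision of low genes, and counting error is only part of the spread between libraries.

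The values called for the fallback test that the design, fixed before the data were examined, gives for normalized values: limma 3.58.1 (R 4.3.3; empirical Bayes with trend and robust settings) on log2(FPKM + 1), over 13474 genes with an FPKM of at least 1 in at least 3 libraries. 1 coefficient per group was fitted to all 9 libraries, and the contrasts were K2133 against scramble, K2231 against scramble, the mean of both knockdown groups against scramble, and K2133 against K2231. P-values were adjusted by Benjamini and Hochberg, and genes were called at an adjusted p under 0.05. The test was run beforehand on simulated data for K2133 against scramble (12956 genes): of 50 changed genes each it recovered 42% at 1.25-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 4-fold. Of 171 calls there, 8 (4.68%) were of unchanged genes, and 0 genes were called by limma when nothing was changed. The changed genes had a mean of at least 5 FPKM and lay outside the gene lists, so recovery of lower genes was not measured.

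The genes named were fixed by a rule before the data were examined: 14 genes of the leukaemia and of myeloid cells whatever their values, the 10 highest and 10 lowest per knockdown group by size of change among called protein coding genes with a mean of at least 5 FPKM in the higher group and no overlap between the groups, the 10 shared by both in each direction, the 8 in each direction between the knockdown groups, and up to 4 members of a list with the smallest adjusted p. A few further list members are named as examples, chosen after their values were seen. 31 gene lists, also fixed beforehand (780 entries found in the tables, 27 not), were tested per contrast with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, which called 0 lists in all 4 contrasts against 7, 9, 8 and 8 with the preset, and fry, which asks whether a list's genes move on balance in 1 direction and called 17, 16, 19 and 16, were run beside it.

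The overlap of the 2 knockdown comparisons was set beside 100 simulations of unchanged groups that share simulated controls (seed 20240). All 9 libraries were redrawn there around 1 mean per gene with each group's own SD, each gene independently. 6 marker lists (epithelial cells, erythroid cells, blood neutrophils and monocytes, T and NK cells, B cells, platelets) were written after the patterns were seen and before their tests. For these lists, reads of every listed gene were approximated as FPKM times exon length times depth, because fewer erythroid and T cell markers gave whole reads, and markers with at least 20 reads were kept. The test of 1 ratio of epithelial reads used 19 markers with at most 3 reads in each scramble library and at least 20 in K2133 replicate 1. Of the kept markers, scramble cells had a mean of at least 1 FPKM in 2 of 37 epithelial, 18 of 24 erythroid, 8 of 20 neutrophil and monocyte, 4 of 12 T and NK cell, 2 of 2 B cell and 2 of 7 platelet markers, and the fixed lists held 3, 6, 4, 0, 0 and 0 of them. 3' UTRs of 10132 genes were searched for 16279 7-mers present in at least 50 genes, whose effect on the difference between the knockdown groups was fitted by regression (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). The p-values of that regression were 1-sided and adjusted by Bonferroni over the 7-mers.

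Alternatives fixed beforehand were quantile normalization, no filter on low values, a stricter filter with a mean of at least 2 FPKM (10406 genes), a pseudocount of 0.1, fits to only the groups compared, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were limma-voom on the recovered reads (12084 genes), median-ratio scaling, quantile normalization for the lists, and subtraction of an epithelial profile, for which K2133 replicate 1 was left out and its excess over the other K2133 libraries was subtracted from the remaining 5 knockdown libraries. Other tests that need raw counts were not used. Circular transcripts, splicing and the junction of F-CircAE were not analysed here.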

Results

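Gene expression was measured by RNA sequencing in Kasumi-1, a human acute myeloid leukaemia line that carries the t(8;21) translocation, which joins RUNX1 (AML1) to RUNX1T1 (ETO). Cells received lentiviral short hairpins against the junction that closes F-CircAE, a circular RNA related to the AML1-ETO fusion, and scramble served as control. The genotype label of the scramble libraries is wild type, and whether those cells were infected with a scramble hairpin is not said, so differences from scramble may include those of infection. The 9 libraries formed 3 groups of 3: scramble control, and 2 knockdown groups with the codes K2133 and K2231, which the labels do not explain. Depth recovered from the values, in M reads (1e6), was 18, 13.7 and 15.4 M reads in the scramble libraries, 15.5, 20.1 and 14.9 M in K2133 and 18.4, 14.6 and 17.4 M in K2231. Values are FPKM, and a log2 fold change is on the log2(FPKM + 1) scale, which understates changes of low genes. The labels do not say whether the 3 replicates of a group were separate cultures or infections, so every adjusted p below measures only the spread between these libraries, which may be technical. Positions are 1-based on hg38.

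The host genes of the fusion were looked at first. RUNX1 (ENSG00000159216, chromosome 21, 34787801 to 36004667) stood at 34, 33.4 and 32.8 FPKM in the scramble libraries, 34.1, 33.2 and 32.3 in K2133 and 36.4, 36.7 and 36.7 in K2231. RUNX1T1 (ENSG00000079102, chromosome 8, 91954967 to 92103286) stood at 15.4, 14.5 and 15.3 FPKM in scramble, 15.7, 15.4 and 14.7 in K2133 and 18.3, 17.6 and 17.1 in K2231. In K2133 neither passed the test (log2 fold change -0.0092, adjusted p = 0.865 for RUNX1 and 0.02, adjusted p = 0.767 for RUNX1T1). In K2231 both were slightly higher, RUNX1 by 0.13 ± 0.0337 (SE, adjusted p = 0.0175) and RUNX1T1 by 0.22 ± 0.0429 (SE, adjusted p = 0.00496), and the RUNX1 call was lost without K2231 replicate 2 (adjusted p = 0.0587). These gene-level values pool linear, fusion and circular transcripts and do not measure the back-splice junction, so they do not check the knockdown of F-CircAE, for which no value is given. The core-binding factor partner CBFB, which pairs with RUNX1, had log2 fold changes of -0.068, adjusted p = 0.227 in K2133 and 0.056, adjusted p = 0.3 in K2231, and passed in K2133 only without scramble replicate 2 (adjusted p = 0.0459).

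**Figure D1:**
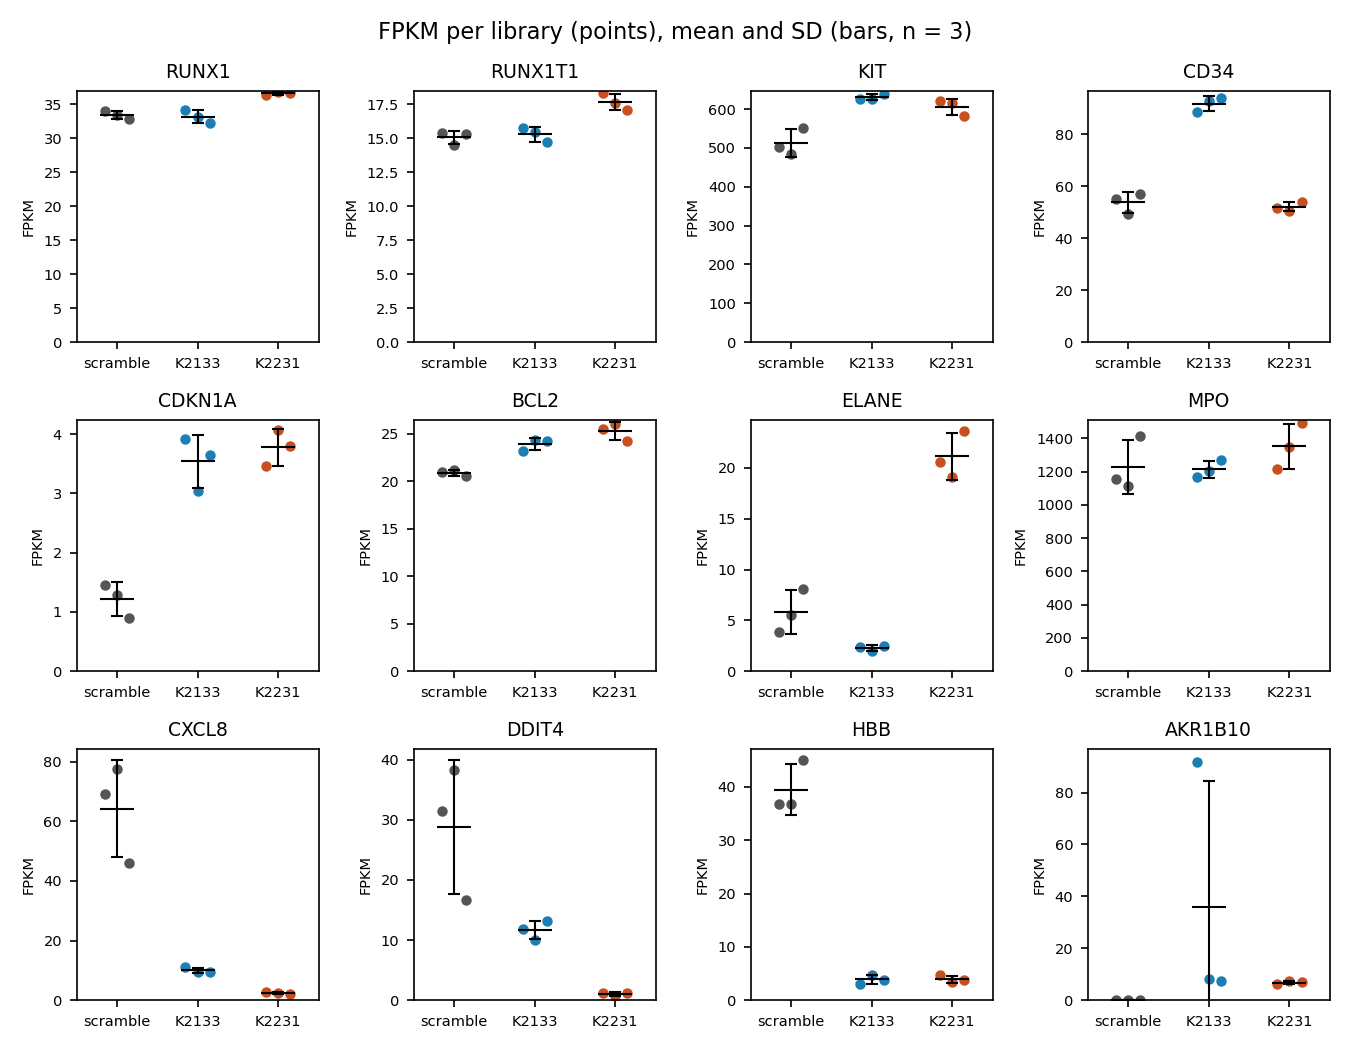
FPKM of 12 genes in each of the 9 libraries, by group: points are libraries, bars the mean and SD of 3. RUNX1 and RUNX1T1 lie close together in all groups, HBB and CXCL8 are lower in both knockdown groups, and CD34 and ELANE differ between K2133 and K2231.

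The comparison of K2133 with scramble asked which transcripts differ in cells given a hairpin against F-CircAE. Most tested genes of the erythroid and megakaryocyte, cholesterol synthesis, and hypoxia and glycolysis lists fell. The progenitor surface marker CD34, the phosphatase gene UBASH3B, the cell cycle inhibitor CDKN1A and the MHC class II genes HLA-DRA and HLA-DPA1 rose. HBB (ENSG00000244734, chromosome 11, 5225464 to 5229395), the beta-globin gene, went from 39.5 ± 4.84 to 3.91 ± 0.874 FPKM (SD, n = 3), a log2 fold change of -3.05 ± 0.148 (SE, adjusted p = 1.43e-05). CD34 (ENSG00000174059, chromosome 1, 207880972 to 207911402) went from 53.8 ± 4.13 to 91.7 ± 2.88 FPKM, a change of 0.76 ± 0.0574 (SE, adjusted p = 6.45e-05). UBASH3B (ENSG00000154127, chromosome 11, 122655675 to 122814473) rose by 1.34 ± 0.0535 (SE, adjusted p = 6.28e-06), and CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) by 1.04 ± 0.112 (SE, adjusted p = 0.000366).

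Among the genes with the largest rises in K2133, GJA1 (ENSG00000152661, chromosome 6, 121435577 to 121449727), which encodes the gap junction protein connexin 43, went from 0.683 ± 0.0566 to 6.23 ± 0.111 FPKM (2.10 ± 0.0607 (SE, adjusted p = 1.47e-06)). CTH, an enzyme of cysteine synthesis, rose by 1.43, the pattern recognition receptor gene CLEC4E by 1.38 and the cell adhesion gene CEACAM6 by 1.37. The receptor tyrosine kinase gene KIT rose from 513 ± 35.1 to 631 ± 7.97 FPKM (0.30 ± 0.0518 (SE, adjusted p = 0.00344)) and the survival gene BCL2 by 0.19, adjusted p = 0.00784. CCND2, a D cyclin gene, fell (-0.28, adjusted p = 0.00334), as did the neutrophil elastase gene ELANE (-1.01 ± 0.2 (SE, adjusted p = 0.00711)). CEBPA (0.056, adjusted p = 0.775), SPI1 (0.23, adjusted p = 0.0723), MYC (0.11, adjusted p = 0.234) and MPO (-0.008, adjusted p = 0.962) did not pass, although SPI1 did without K2231 replicate 3 (adjusted p = 0.014), and ITGAM was too low to be tested. Large falls beside those of red-cell genes were in CXCL8 (-2.53), a neutrophil chemoattractant, the chemokine genes CCL4L2 (-2.43) and CCL3L1 (-1.82), SERPINA1 (-1.93), which encodes alpha-1 antitrypsin, and ALOX5AP (-1.77) of leukotriene synthesis. CCL4L2 and CCL3L1, like the alpha-globin genes, have near-identical copies, so how reads were shared among copies is uncertain.

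A group of genes stood highest in K2133 replicate 1 and lower in the other knockdown libraries. AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408), an aldo-keto reductase, was listed at 0 in all 3 scramble libraries, at 91.8, 8.26 and 7.39 FPKM in K2133 and at 6.17, 7.25 and 6.85 in K2231. S100A10, a calcium-binding protein family gene, was at 0.0721, 0.0943 and 0 FPKM in scramble and 20.2, 2.38 and 1.7 in K2133. The log2 fold changes of S100A10 (2.45), S100A6 (2.30), ALDH1A1 (2.24) and GPX2 (1.86) were 1.52, 1.29, 1.34 and 1.06 without that library (adjusted p = 0.000852, 0.00326, 0.00304 and 0.00248). They then passed in K2231 too, at 1.38, 1.17, 1.28 and 0.87 (adjusted p = 0.000443 to 0.00191). The call of S100A10 was lost without scramble replicate 1, 2 or 3 (adjusted p = 0.0595 to 0.0646), that of ALDH1A1 without scramble replicate 1, 2 or 3 (adjusted p = 0.0671 to 0.0783), that of S100A6 without scramble replicate 1, 2 or 3 or K2231 replicate 1, 2 or 3 (adjusted p = 0.0576 to 0.101) and that of GPX2 without scramble replicate 1, 2 or 3 or K2231 replicate 1, 2 or 3 (adjusted p = 0.0532 to 0.0988). In the same libraries, 37 epithelial marker genes, such as the keratin gene KRT8, summed to 1030 reads per M in K2133 replicate 1, 130 and 114 in the other K2133 libraries, 99.9, 107 and 118 in K2231, and 33.9, 38.3 and 27.4 in scramble. Not all were raised, ITGB4 having a ratio of knockdown to scramble reads of 0.78 over both groups. ITGB4, LAMA5, CYR61 and ITGA3 gave most of the scramble sum. Of the 4 tested epithelial, stromal and kidney-line genes, 3 passed as higher and 1 as lower in K2133 (list adjusted p = 0.329, 3 and 1 adjusted over the list alone), and in K2231 1 as higher and 0 as lower (list adjusted p = 0.217, 1 and 0 adjusted over the list alone), a list that passed in K2231 without K2133 replicate 1 (adjusted p = 0.027).

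Of the 31 gene lists, 7 were called in K2133, all lower. Among 23 tested cholesterol synthesis genes, 0 rose and 21 fell (0 and 21 adjusted over the list alone), including MSMO1 (-0.90) and HMGCS1 (-0.80). The cholesterol list had a camera adjusted p = 1.46e-11 (adjusted p = 0.113 with an estimated correlation). Of 28 hypoxia and glycolysis genes, 1 rose and 20 fell (1 and 21 adjusted over the list alone), among them the glucose transporter gene SLC2A1 (-1.08), MXI1 (-1.08), PGAM1 (-0.39) and PGK1 (-0.70). The hypoxia and glycolysis list had a camera adjusted p = 6.37e-09 (adjusted p = 0.443 with an estimated correlation). Of 11 erythroid and megakaryocyte genes, 0 rose and 9 fell (0 and 9 adjusted over the list alone), with HBB (-3.05), ALAS2 (-2.58), SLC4A1 (-1.57) and AHSP (-1.89) lower, ALAS2 being the first enzyme of haem synthesis in red cells. The erythroid list had a camera adjusted p = 3.22e-07 (adjusted p = 0.113 with an estimated correlation). Transcripts of other blood cells were mixed: over both knockdown groups the ratio of knockdown to scramble reads was 0.17 for S100A8 and 0.176 for IL7R, but 1.98 for FGL2 and 1.31 for TRBC1. TRBC1 stood at 27.3 to 32.3 FPKM in scramble and 36.5 to 43.2 in the knockdown libraries, so it says little about other blood cells. The ratio was under 0.5 for 13 of 20 neutrophil and monocyte markers and 5 of 12 T and NK cell markers. In K2133 alone, median ratios were 0.227 over 24 erythroid markers, 0.362 over 20 neutrophil and monocyte markers, 0.821 over 12 T and NK cell markers, 1.15 over 2 B cell markers and 1.2 over 7 platelet markers.

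Myeloid maturation genes also fell in K2133, beside the blood neutrophil and monocyte markers (median ratio 0.362), 4 of which are in the fixed lists. Of 11 primary granule genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone), with CFD (-1.02), SRGN (-1.32) and PRTN3 (-1.27) lower and the lysozyme gene LYZ (0.84) higher. The primary granule list had a camera adjusted p = 0.0113 (adjusted p = 0.443 with an estimated correlation). Of 10 monocyte and neutrophil maturation genes, 1 rose and 6 fell (1 and 7 adjusted over the list alone): the Fc receptor gene FCGR1A (-1.28) and S100A9 (-1.35) fell and the G-CSF receptor gene CSF3R (0.58) rose. The maturation list had a camera adjusted p = 0.0113 (adjusted p = 0.42 with an estimated correlation). Of 29 genes of the unfolded protein and ATF4 response, 1 rose and 13 fell (2 and 14 adjusted over the list alone), with XBP1 (-0.45), TRIB3 (-0.48), EDEM1 (-0.44) and MTHFD2 (-0.45) among the latter. The unfolded protein list had a camera adjusted p = 0.0113 (adjusted p = 0.443 with an estimated correlation). Of 73 cytosolic ribosomal protein genes, 6 rose and 27 fell (7 and 33 adjusted over the list alone), such as RPL14 (-0.32), RPL34 (-0.40) and RPL36 (-0.46) lower and RPL28 (0.28) higher, but with quantile normalization the list was no longer called (adjusted p = 0.711). The ribosomal protein list had a camera adjusted p = 0.00134 (adjusted p = 0.756 with an estimated correlation). Many of these genes have processed pseudogenes that can share reads with them.

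In K2133, limma called 3952 of 13474 tested genes, 1907 higher and 2045 lower. Without K2133 replicate 2 the higher ones numbered 1197, and with quantile normalization 2054 were higher and 1955 lower. In the main fit 154 changed by at least 2-fold, 54 higher and 100 lower. The median size of a called log2 change was 0.31. The 3 K2133 libraries did not overlap the 3 scramble libraries in 6103 genes (45.3%), where chance gives 10%.

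K2231 was compared with scramble for the same question. Most tested genes of the hypoxia and glycolysis, NF-kB and inflammatory, and cholesterol synthesis lists fell, as did the globin genes HBB and HBA2. Of 13 mitochondrially encoded transcripts 9 rose, a list call lost with quantile normalization. The elastase gene ELANE, the integrin gene ITGA4 and UBASH3B rose too. DDIT4 (ENSG00000168209, chromosome 10, 72273920 to 72276036), a hypoxia- and stress-induced inhibitor of mTORC1, went from 28.8 ± 11.1 to 1.02 ± 0.283 FPKM (SD, n = 3), a log2 fold change of -3.82 ± 0.268 (SE, adjusted p = 5.2e-05). CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716) went from 64.2 ± 16.2 to 2.35 ± 0.291 FPKM (-4.25 ± 0.171 (SE, adjusted p = 3.32e-06)). ELANE (ENSG00000197561, chromosome 19, 851014 to 856247) went from 5.82 ± 2.15 to 21.1 ± 2.31 FPKM (1.74 ± 0.2 (SE, adjusted p = 0.000436)).

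Further falls of K2231 were in PFKFB4 (-3.42), a regulator of glycolysis, the lipid droplet gene PLIN2 (-3.42), the glucose transporter gene SLC2A3 (-2.84), the mitophagy gene BNIP3 (-2.49), HBB (-3.04), HBA2 (-2.59), ALAS2 (-2.56) and CCL4L2 (-2.65). Rises were in KCNJ11 (1.31), a potassium channel subunit, the growth factor gene HGF (1.27), ITGA4 (1.23), UBASH3B (1.22), IGFBP7 (1.20), CERKL (1.07), RASGRP2 (1.0), an exchange factor of Rap1, and MACROD1 (0.99). AKR1B10, listed at 0 in scramble, passed too, but not without scramble replicate 1 or 2 or K2231 replicate 2 or 3 (adjusted p = 0.0519 to 0.0556). KIT rose to 606 ± 20.7 FPKM (0.24 ± 0.0518 (SE, adjusted p = 0.00696)), BCL2 by 0.26 ± 0.0386 (SE, adjusted p = 0.00125) and CDKN1A from 1.21 ± 0.289 to 3.78 ± 0.311 FPKM (1.12 ± 0.112 (SE, adjusted p = 0.000195)). CD34 stood at 52.1 ± 1.76 FPKM and did not pass (-0.043, adjusted p = 0.588). CCND2 was called higher (0.15, adjusted p = 0.0371), a call lost without scramble replicate 1 or 3, K2133 replicate 1 or 2 or K2231 replicate 1 (adjusted p = 0.0545 to 0.112). CEBPA (0.16, adjusted p = 0.359), SPI1 (0.087, adjusted p = 0.46), MYC (0.18, adjusted p = 0.0591) and MPO (0.14, adjusted p = 0.293) did not pass, although without scramble replicate 3 both MYC (adjusted p = 0.0238) and MPO (adjusted p = 0.0412) did.

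Of the 31 gene lists, 9 were called in K2231, 3 higher and 6 lower. Of 28 hypoxia and glycolysis genes, 0 rose and 27 fell (0 and 27 adjusted over the list alone), including SLC2A1 (-1.19), PGAM1 (-0.65), PGK1 (-1.12) and DDIT4 (-3.82). The hypoxia and glycolysis list had a camera adjusted p = 8.17e-17 (adjusted p = 0.404 with an estimated correlation). The scramble libraries differed among themselves in this list, with a median difference of 0.41 on the log2 scale between scramble replicates 2 and 3. NF-kB and inflammatory genes numbered 16, of which 1 rose and 12 fell (2 and 12 adjusted over the list alone), with the adhesion molecule gene ICAM1 (-1.39), CXCL8 (-4.25), CCL5 (-0.85) and NFKB2 (-1.0) lower; in K2133, 1 rose and 7 fell (list adjusted p = 0.137, 3 and 7 adjusted over the list alone). The NF-kB list had a camera adjusted p = 3.19e-05 (adjusted p = 0.191 with an estimated correlation). Of 23 cholesterol synthesis genes, 0 rose and 15 fell (0 and 17 adjusted over the list alone), such as MSMO1 (-0.92), HMGCS1 (-0.89) and TM7SF2 (-0.75). The cholesterol list had a camera adjusted p = 3.04e-06 (adjusted p = 0.296 with an estimated correlation). Of the erythroid and megakaryocyte genes, 0 rose and 8 fell (0 and 8 adjusted over the list alone), HBB, ALAS2, SLC4A1 (-1.68) and AHSP (-2.16) among them, beside median marker ratios in K2231 of 0.16 for erythroid, 0.887 for T and NK cells, 0.688 for B cells and 1.11 for platelets. The erythroid list had a camera adjusted p = 2.75e-05 (adjusted p = 0.191 with an estimated correlation). Of the monocyte and neutrophil maturation genes, 1 rose and 7 fell (1 and 7 adjusted over the list alone), beside a median ratio of 0.468 for blood neutrophil and monocyte markers, with FCGR1A (-0.88) and FCGR2A (-0.95) lower and CSF3R (0.72) higher. The maturation list had a camera adjusted p = 0.0167 (adjusted p = 0.362 with an estimated correlation). Of the cytosolic ribosomal protein genes, 2 rose and 33 fell (3 and 35 adjusted over the list alone), such as RPSA (-0.38), RPS12 (-0.51) and RPS2 (-0.27), a call lost with quantile normalization (adjusted p = 0.854). The ribosomal protein list had a camera adjusted p = 3.19e-05 (adjusted p = 0.722 with an estimated correlation).

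The mitochondrially encoded genes were 1 of the 3 lists called higher in K2231: of 13, 9 rose and 0 fell (10 and 0 adjusted over the list alone), led by MT-ND3 (0.60), MT-CYB (0.47), MT-ND2 (0.65) and MT-ND4L (0.42). The mitochondrial list had a camera adjusted p = 0.00109 (adjusted p = 0.506 with an estimated correlation). Quantile normalization ended that call (adjusted p = 0.0522) and, among single members, put MT-CO1 at -0.016. In K2133, 5 rose and 0 fell (list adjusted p = 0.137, 5 and 0 adjusted over the list alone), and the list passed without scramble replicate 3 (adjusted p = 0.00739). Mitochondrial transcripts took 4.11 ± 0.350% of reads in scramble, 4.25 ± 0.0319% in K2133 and 4.69 ± 0.126% in K2231 (SD, n = 3). Of 16 genes raised in or marking t(8;21) leukaemia, 9 rose and 3 fell in K2231 (9 and 3 adjusted over the list alone), with UBASH3B (1.22), CDKN1A (1.12) and PAX5 (0.48) higher and the plakoglobin gene JUP (-0.73) lower. The t(8;21) list had a camera adjusted p = 0.0229 (adjusted p = 0.362 with an estimated correlation). In K2133, 6 rose and 2 fell of this list (list adjusted p = 0.185, 7 and 3 adjusted over the list alone). CAV1, a member of this list, is also 1 of the epithelial markers, at 0 FPKM in scramble and 0.826 to 1.19 in K2231. Of 30 MYC and ribosome biogenesis genes, 10 rose and 2 fell in K2231 (10 and 2 adjusted over the list alone). The MYC list had a camera adjusted p = 0.0453 (adjusted p = 0.817 with an estimated correlation). The higher ones included MYBBP1A (0.53) and POLR1A (0.28), and the lower ones were lactate dehydrogenase A, LDHA (-0.93), and nucleophosmin, NPM1 (-0.27). The MYC list call was lost without scramble replicate 2, K2133 replicate 2 or 3 or K2231 replicate 1 or 2 (adjusted p = 0.0507 to 0.236). In K2133, 3 rose and 3 fell of the list (list adjusted p = 0.31, 3 and 2 adjusted over the list alone), which passed without scramble replicate 3 (adjusted p = 0.021).

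In K2231, limma called 4886 of 13474 genes, 2261 higher and 2625 lower (2604 and 2434 with quantile normalization). In the main fit 216 changed by at least 2-fold, 50 higher and 166 lower. The median size of a called log2 change was 0.32. The groups of 3 did not overlap in 6451 genes (47.9%), where chance gives 10%.

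**Figure D2:**
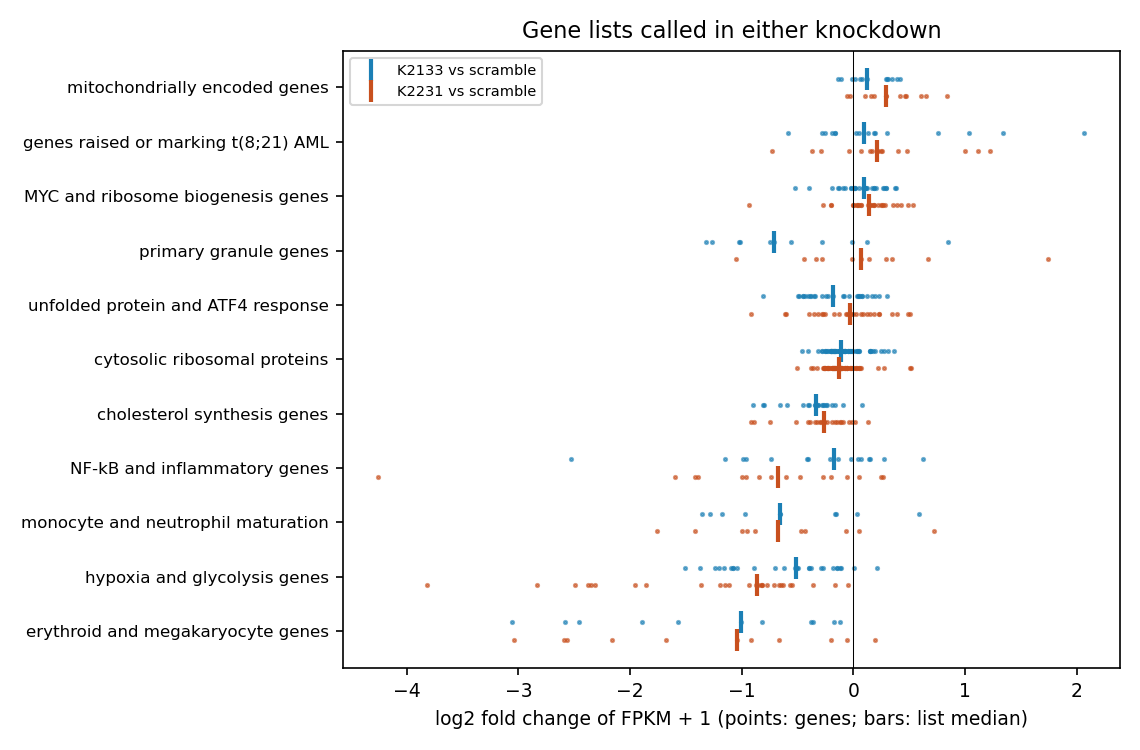
Log2 fold changes against scramble of the members of 11 gene lists called in either knockdown group: points are genes and bars the list medians. Hypoxia and glycolysis, cholesterol synthesis and erythroid genes lie mostly below 0 in both K2133 and K2231; all list calls are lost with an estimated correlation between genes.

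Several lists were not called in 1 or both knockdown groups in the main fit, although single members moved. The share of all tested genes called was 29.3% in K2133 and 36.3% in K2231, so called members are found in most lists. Of 18 antigen presentation genes, 8 rose and 4 fell in K2133 (list adjusted p = 0.0575, 8 and 4 adjusted over the list alone), the MHC class II genes HLA-DRA (1.26), HLA-DPA1 (1.02) and CD74 (0.80) among the higher ones, and the list passed without scramble replicate 2 or K2133 replicate 2 (adjusted p = 0.0355 to 0.0448). It passed too with no filter (adjusted p = 0.0195), quantile normalization (adjusted p = 0.043) or voom (adjusted p = 0.0468). In K2231, 4 rose and 7 fell (list adjusted p = 0.421, 4 and 9 adjusted over the list alone), with B2M (-0.52), CD74 (-0.53) and HLA-E (-0.59) lower. Of 48 nuclear oxidative phosphorylation genes, 6 rose and 14 fell in K2133 (list adjusted p = 0.168, 6 and 14 adjusted over the list alone), with the ATP synthase gene ATP5F1B (-0.85) lower. In K2231, 17 rose and 5 fell (list adjusted p = 0.0641, 17 and 5 adjusted over the list alone), with COX7C (0.52) and NDUFA3 (0.46) higher and ATP5F1B (-0.54) lower, and the list passed without scramble replicate 3 or K2231 replicate 3 (adjusted p = 0.0114 to 0.0239) or with no filter (adjusted p = 0.0164). Of 26 BCL2 family and caspase genes, 5 rose and 9 fell in K2133 (list adjusted p = 0.168, 5 and 9 adjusted over the list alone) and 5 rose and 11 fell in K2231 (list adjusted p = 0.0744, 5 and 11 adjusted over the list alone). The K2231 list passed with voom (adjusted p = 0.0408) or no filter (adjusted p = 0.00605). The anti-apoptotic BCL2L1 fell in both (-0.50 and -0.56), and the cytochrome c gene CYCS fell in both (-0.42 and -1.50). Of 29 unfolded protein and ATF4 response genes, 5 rose and 8 fell in K2231 (list adjusted p = 0.7, 5 and 8 adjusted over the list alone). Of 11 primary granule genes, 2 rose and 2 fell in K2231 (list adjusted p = 0.797, 4 and 2 adjusted over the list alone), ELANE (1.74) being higher and SRGN (-1.05) lower.

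Cell cycle and lineage lists were mixed. Of 33 G1/S replication genes, 8 rose and 1 fell in K2133 (list adjusted p = 0.168, 8 and 1 adjusted over the list alone), with E2F1 (0.51), MCM5 (0.41) and MCM7 (0.35) higher, and the list passed without scramble replicate 3 (adjusted p = 0.0107). In K2231, 3 rose and 4 fell (list adjusted p = 0.93, 3 and 4 adjusted over the list alone). Of 31 G2/M mitosis genes, 4 rose and 4 fell in K2133 (list adjusted p = 0.664, 4 and 4 adjusted over the list alone) and 11 rose and 1 fell in K2231 (list adjusted p = 0.054, 11 and 1 adjusted over the list alone), with CENPF (0.25), CCNB1 (0.26) and ECT2 (0.34) higher, and the K2231 list passed without scramble replicate 3 or K2231 replicate 3 (adjusted p = 0.00476 to 0.0353). It passed too with no filter (adjusted p = 0.0115), median-ratio scaling (adjusted p = 0.0479) or an epithelial profile subtracted (adjusted p = 0.0491). Of 13 cell cycle inhibitors and D cyclins, 5 rose and 4 fell in K2133 (list adjusted p = 0.551, 6 and 4 adjusted over the list alone) and 5 rose and 4 fell in K2231 (list adjusted p = 0.984, 6 and 6 adjusted over the list alone). CDKN2A rose in both (0.52 and 0.44) and CCND1 fell in both (-0.51 and -1.03). Of 20 p53 targets, 7 rose and 3 fell in K2133 (list adjusted p = 0.249, 8 and 6 adjusted over the list alone) and 3 rose and 6 fell in K2231 (list adjusted p = 0.984, 4 and 6 adjusted over the list alone), and ZMAT3 was higher in both (0.66 and 0.42). Of 10 genes that AML1-ETO represses, 2 rose and 3 fell in K2133 (list adjusted p = 0.717, 3 and 4 adjusted over the list alone) and 3 rose and 2 fell in K2231 (list adjusted p = 0.217, 3 and 2 adjusted over the list alone). LAPTM5 was lower in both (-0.77 and -1.02) and CSF3R higher in both. Of 14 stem and progenitor genes, 4 rose and 2 fell in K2133 (list adjusted p = 0.683, 4 and 3 adjusted over the list alone), with CD34 and LMO2 (0.44) higher. In K2231, 4 rose and 2 fell (list adjusted p = 0.7, 4 and 2 adjusted over the list alone), with FLT3 (0.63) higher and MYCN (-1.69) lower. Of 3 mast cell, basophil and eosinophil genes, 2 rose and 0 fell in K2133 (list adjusted p = 0.249, 2 and 0 adjusted over the list alone) and 2 rose and 0 fell in K2231 (list adjusted p = 0.258, 2 and 1 adjusted over the list alone), where the tryptase gene TPSB2 (1.18) rose. Of 5 lymphoid genes, 0 rose and 1 fell in K2133 (list adjusted p = 0.603, 1 and 1 adjusted over the list alone) and 2 rose and 2 fell in K2231 (list adjusted p = 0.797, 2 and 2 adjusted over the list alone), CD4 being lower in both (-0.50 and -1.15), and the K2231 list passed as lower with no filter (adjusted p = 0.013). The median, mean and test of a list differed in sign for the stem and progenitor and the cell cycle inhibitor lists in both groups, and for the lymphoid and G1/S lists in K2231.

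The overlap of the 2 knockdown groups was examined next. The globin genes HBB and HBM, the cholesterol enzyme genes MSMO1 and HMGCS1 and the chemokine genes CXCL8 and CCL4L2 fell in both. KCNJ11, UBASH3B and ITGA4 rose in both. Among genes raised in both by the largest margin were KCNJ11 (1.24 in K2133 and 1.31 in K2231), B4GALT6 (0.88 and 0.87), LRFN4 (0.83 and 0.92), EMB (0.83 and 0.92), LOXL3 (0.81 and 0.85), the endothelial growth regulator EGFL7 (0.83 and 0.79), IGFBP7 (0.79 and 1.20) and ITGA4 (0.76 and 1.23). Among those lowered in both were HBM (-2.02 and -2.04), a further globin gene, AHSP (-1.89 and -2.16), the chaperone of alpha-globin, SERPINA1 (-1.93 and -1.74) and ALOX5AP (-1.77 and -1.92).

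Of all tested genes, 2309 were called in both comparisons, against 1433 for independent lists and a mean of 0.42 in 100 simulations of unchanged groups sharing simulated controls. Of these, 962 were higher in both (320 for independent lists, 0.17 simulated), 1176 were lower in both (398 and 0.25), 97 were higher in K2133 and lower in K2231 (372 and 0) and 74 were the reverse (343 and 0). The genes higher in both numbered 606 without K2133 replicate 2 and 604 with no filter, and with quantile normalization 1121 were higher and 1056 lower in both. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.619 (simulated mean 0.540, range 0.485 to 0.582) and a Spearman rho of 0.556 (simulated mean 0.537, range 0.515 to 0.557). The covariance was 0.0699 against 0.0140 simulated, a difference of 0.0559. The sign was shared by 70.3% of genes, against 70.4% simulated. Both comparisons use the same 3 scramble libraries, too few to be split into parts of at least 2, so part of the excess may come from the shared controls. The simulated groups had almost no calls, so their overlap is near 0 whatever the controls share and does not size that part. Genes were also drawn independently of each other. The simulated correlations and covariance thus leave out any shift of many genes together in the scramble libraries, and do not size that part either.

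**Figure D3:**
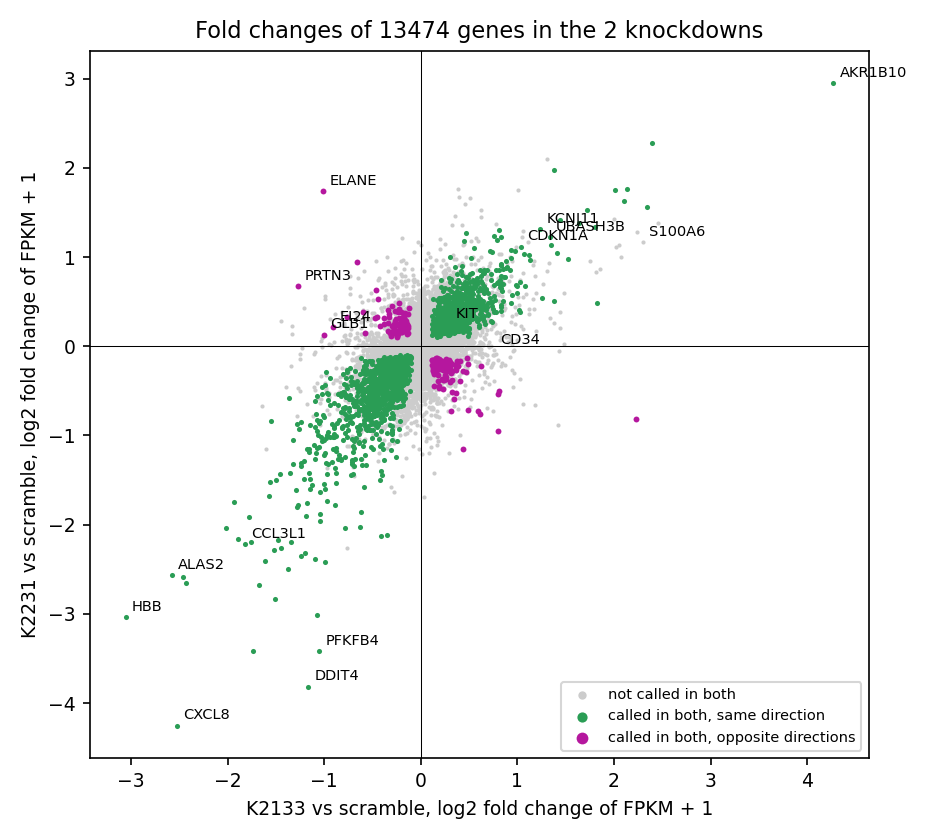
Log2 fold change against scramble of 13474 genes, K2133 on the horizontal and K2231 on the vertical axis: green points were called in both in the same direction (2138 genes), magenta points in opposite directions (171) and grey points not in both. Both axes share the scramble libraries, which alone gives a correlation.

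With both knockdown groups set together against scramble, HBB fell by 3.05 ± 0.128 (SE, adjusted p = 4.71e-06), DDIT4 by 2.49 ± 0.232 (SE, adjusted p = 0.000205) and CXCL8 by 3.39 ± 0.148 (SE, adjusted p = 6.4e-06) on the log2 scale, and UBASH3B rose by 1.28 ± 0.0463 (SE, adjusted p = 2.44e-06). Each value is the mean of the changes in K2133 and K2231. For DDIT4 and CXCL8 these were unlike, the fall being larger in K2231, and the SE leaves out that difference. In this contrast limma called 4738 genes, 2203 higher and 2535 lower (2473 and 2352 with quantile normalization). In the main fit 148 changed by at least 2-fold (42 higher, 106 lower), and the median called log2 change was 0.27. A fit that pooled the 6 knockdown libraries into 1 group called 2538. Of the 31 lists, 8 were called. Lower were hypoxia and glycolysis genes (0 rose and 26 fell, 0 and 26 adjusted over the list alone), cholesterol synthesis genes (0 rose and 20 fell, 0 and 21 adjusted over the list alone), erythroid and megakaryocyte genes (0 rose and 9 fell, 0 and 9 adjusted over the list alone) and NF-kB and inflammatory genes (1 rose and 11 fell, 2 and 11 adjusted over the list alone). The hypoxia and glycolysis list had a camera adjusted p = 1.21e-14 (adjusted p = 0.423 with an estimated correlation). The cholesterol list had a camera adjusted p = 3.72e-10 (adjusted p = 0.161 with an estimated correlation). The erythroid list had a camera adjusted p = 8.4e-07 (adjusted p = 0.161 with an estimated correlation). The NF-kB list had a camera adjusted p = 0.000851 (adjusted p = 0.202 with an estimated correlation). Monocyte and neutrophil maturation genes (1 rose and 7 fell, 1 and 7 adjusted over the list alone) and cytosolic ribosomal protein genes (5 rose and 38 fell, 5 and 40 adjusted over the list alone) were lower as well, the latter not with quantile normalization (adjusted p = 0.671). Over both groups, the median ratio to scramble was 0.191 for erythroid and 0.376 for blood neutrophil and monocyte markers. The maturation list had a camera adjusted p = 0.00707 (adjusted p = 0.275 with an estimated correlation). The ribosomal protein list had a camera adjusted p = 4.01e-05 (adjusted p = 0.71 with an estimated correlation). Higher were mitochondrially encoded genes (7 rose and 0 fell, 8 and 0 adjusted over the list alone), not with quantile normalization (adjusted p = 0.114), and genes raised in or marking t(8;21) leukaemia (8 rose and 2 fell, 9 and 2 adjusted over the list alone). The mitochondrial list had a camera adjusted p = 0.00667 (adjusted p = 0.584 with an estimated correlation). The t(8;21) list had a camera adjusted p = 0.046 (adjusted p = 0.415 with an estimated correlation). The t(8;21) call was lost without scramble replicate 3 or K2231 replicate 1 or 3 (adjusted p = 0.0522 to 0.104), and with no filter on low values (adjusted p = 0.0766), with the replicate number as a block (adjusted p = 0.0661) or with an epithelial profile subtracted (adjusted p = 0.104). Its member CAV1 is also an epithelial marker, at 0 FPKM in scramble, 14.9 in K2133 replicate 1 and 0.826 to 1.19 in the other knockdown libraries. Primary granule genes passed as lower without scramble replicate 1 (adjusted p = 0.0415), the epithelial, stromal and kidney-line genes as higher without K2133 replicate 1 (adjusted p = 0.0391), the G2/M genes as higher without scramble replicate 3 (adjusted p = 0.0227) and the MYC and ribosome biogenesis genes as higher without scramble replicate 3 (adjusted p = 0.00189), with no filter (adjusted p = 0.0339) or with quantile normalization (adjusted p = 0.0497). The BCL2 family and caspase genes and the unfolded protein genes passed as lower with voom (adjusted p = 0.0406 and 0.0371) or no filter (adjusted p = 0.0064 and 0.0153). With no filter the lymphoid and the immediate early genes passed as lower too (adjusted p = 0.0152 each).

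K2133 and K2231 were then compared directly, to see which differences from scramble were specific to 1 of the 2 groups. The granule protease genes ELANE and PRTN3 were lower in K2133 than in K2231. Most tested hypoxia and glycolysis genes, 9 of 16 NF-kB and inflammatory genes, HLA-DRA, HLA-DPA1, CD34 and MYCN were higher. ELANE was at 2.28 ± 0.264 FPKM in K2133 and 21.1 ± 2.31 in K2231 (SD, n = 3), a log2 difference of -2.75 ± 0.2 (SE, adjusted p = 9.99e-05), and PRTN3, the proteinase 3 gene, differed by -1.94 ± 0.202 (SE, adjusted p = 0.000384). DDIT4 differed by 2.65 ± 0.268 (SE, adjusted p = 0.000337), CD34 by 0.80 ± 0.0574 (SE, adjusted p = 7.44e-05) and MYCN, a MYC family gene, by 1.73 ± 0.128 (SE, adjusted p = 9.02e-05).

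Genes higher in K2133 than in K2231 by a large margin also included PFKFB4 (2.37), IKZF2 (1.77), which encodes the transcription factor Helios, CXCL8 (1.73), the transglutaminase gene TGM5 (1.72), IGLL1 (1.71) of the surrogate light chain and PLIN2 (1.68). Lower were the nucleoside transporter gene SLC28A3 (-1.55), DEGS1 (-1.21), a desaturase of ceramide synthesis, GLB1 (-1.13), the lysosomal beta-galactosidase, EI24 (-1.12), PLPPR3 (-1.11) and MILR1 (-1.10). CCND2 was lower by -0.44 ± 0.0485 (SE, adjusted p = 0.000417) and RUNX1T1 by -0.20 ± 0.0429 (SE, adjusted p = 0.00988). RUNX1 was called lower (-0.14, adjusted p = 0.0163), a call lost without K2133 replicate 2 or 3 or K2231 replicate 2 (adjusted p = 0.0571 to 0.0674).

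Of the 31 lists, 8 were called between K2133 and K2231, 4 in each direction. Of 28 hypoxia and glycolysis genes, 25 were higher and 0 lower in K2133 (25 and 1 adjusted over the list alone), such as DDIT4 (2.65), PKM (0.42), BNIP3L (1.23) and HK1 (0.55). The hypoxia and glycolysis list had a camera adjusted p = 4.85e-10 (adjusted p = 0.686 with an estimated correlation). Of 18 antigen presentation genes, 11 were higher and 1 lower (14 and 1 adjusted over the list alone), with CD74 (1.33), HLA-DPA1 (0.64) and B2M (0.34) higher and the class I regulator NLRC5 (-0.56) lower. The antigen presentation list had a camera adjusted p = 2.05e-05 (adjusted p = 0.138 with an estimated correlation). Of 16 NF-kB and inflammatory genes, 9 were higher and 1 lower (10 and 1 adjusted over the list alone), including ICAM1 (0.99), TNFAIP3 (0.65) and NFKBIA (0.41). The NF-kB list had a camera adjusted p = 0.000708 (adjusted p = 0.272 with an estimated correlation). Of 48 nuclear oxidative phosphorylation genes, 0 were higher and 17 lower (0 and 19 adjusted over the list alone), for example ATP5MC3 (-0.41), NDUFA8 (-0.32), NDUFA3 (-0.36) and ATP5PF (-0.36). The oxidative phosphorylation list had a camera adjusted p = 8.95e-06 (adjusted p = 0.662 with an estimated correlation). Of 11 primary granule genes, 1 was higher and 5 were lower (1 and 5 adjusted over the list alone), ELANE, PRTN3, CFD (-1.01) and AZU1 (-0.85) among the lower ones. The primary granule list had a camera adjusted p = 0.0206 (adjusted p = 0.686 with an estimated correlation).

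The remaining 3 lists called between the knockdown groups were the mitochondrially encoded, G1/S replication and unfolded protein genes. Of 13 mitochondrially encoded genes, 0 were higher and 1 lower in K2133 (0 and 1 adjusted over the list alone), a call lost with quantile normalization (adjusted p = 0.252) or no filter (adjusted p = 0.108). The mitochondrial list had a camera adjusted p = 0.0206 (adjusted p = 0.686 with an estimated correlation). Of 33 G1/S replication genes, 7 were higher and 2 lower (9 and 2 adjusted over the list alone), with CHAF1A (0.31) and RRM2 (0.35) higher and cyclin E1, CCNE1 (-0.58), lower. The G1/S list had a camera adjusted p = 0.0468 (adjusted p = 0.719 with an estimated correlation). That call was lost without scramble replicate 1, K2133 replicate 1, 2 or 3 or K2231 replicate 1 or 3 (adjusted p = 0.0518 to 0.0919). It was lost too with the replicate number as a block (adjusted p = 0.0511), with voom (adjusted p = 0.0681) and with an epithelial profile subtracted (adjusted p = 0.0622). Of 29 unfolded protein and ATF4 response genes, 3 were higher and 10 lower (4 and 10 adjusted over the list alone), such as XBP1 (-0.43), EDEM1 (-0.40) and PDIA6 (-0.30), a call lost without scramble replicate 1, K2133 replicate 2 or K2231 replicate 3 (adjusted p = 0.0543 to 0.0903) or with the replicate number as a block (adjusted p = 0.0511). The unfolded protein list had a camera adjusted p = 0.0468 (adjusted p = 0.686 with an estimated correlation). The cholesterol synthesis genes passed as lower in K2133 without K2231 replicate 3 (adjusted p = 0.0289) or with no filter (adjusted p = 0.0344), and with no filter the p53 targets (adjusted p = 0.0458) and the cell cycle inhibitors and D cyclins (adjusted p = 0.031) passed as higher. Between the knockdown groups limma called 3750 of 13474 genes, 2009 higher and 1741 lower in K2133. The lower ones numbered 1134 without K2231 replicate 2, and with quantile normalization 1922 were higher and 1989 lower. In the main fit 107 differed by at least 2-fold (67 higher, 40 lower), with a median called log2 difference of 0.31. The groups of 3 did not overlap in 6421 genes (47.7%), where chance gives 10%.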

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

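Of the tests of explanations in this part, the one for GC content and exon length was chosen before its result was seen, and the others only after. limma's contrasts and the alternatives in the last paragraph were fixed before the data were examined. Intervals of a median in this part come from 2000 resamplings of the genes of a list. Those genes are not independent, and the spread between libraries does not enter. Such an interval is therefore no confidence interval of a group effect.

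Epithelial transcripts stood apart in the knockdown libraries. Over 37 markers such as KRT8 (10.4 FPKM in K2133 replicate 1, 1.11 to 1.45 in the other knockdown libraries, 0 in scramble), the reads per M summed to 1030 in K2133 replicate 1, 99.9 to 130 in the other knockdown libraries and 27.4 to 38.3 in scramble. The sum was 8.47 times higher in K2133 replicate 1 than in the mean of K2133 replicates 2 and 3, which argues against an effect of the K2133 hairpin as the source of that level. A candidate explanation is RNA or reads of 1 epithelial source at 1 share per library. It was tested over 19 markers, kept for at most 3 reads in each scramble library and at least 20 in K2133 replicate 1. The ratio of K2133 replicate 1 to the other knockdown libraries varied between genes beyond counting error (chi-square per degree of freedom 8.28, SD of the log2 ratio 0.43). That argues against 1 exact ratio with counting error alone. It cannot decide on 1 source with further variation between genes, which was not tested. Why the other 5 knockdown libraries carry these reads at a lower share stays open, and a biological effect of the knockdown on them was not tested.

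Erythroid markers had a median ratio to scramble of 0.227 in K2133 and 0.16 in K2231, and blood neutrophil and monocyte markers of 0.362 and 0.468, while B cell (1.15 and 0.688) and platelet markers (1.2 and 1.11) were not lower in both. A mean of at least 1 FPKM in scramble was reached by 2 of 2 B cell and 2 of 7 platelet markers. Other platelet markers had few reads over the scramble libraries, such as TREML1 (1) and CLEC1B (6). The B cell and platelet lists therefore say little about blood reads. Erythroid markers did not keep 1 ratio of knockdown to scramble, from 0.0992 for HBB and 0.151 for ALAS2 to 0.864 for GYPC and 1.05 for XK (chi-square per degree of freedom 392), so a single share of blood RNA per group without a contribution of the cells themselves is excluded. Reads of peripheral blood in the scramble libraries may explain part of it. The median ratio of T and NK cell markers was 0.857 (interval 0.307 to 1.34, 12 genes), which mixes markers the cells express with others. In scramble and knockdown alike, 4 had a mean of at least 1 FPKM, such as TRBC1 (ratio 1.31) and CD247 (1.37), and say little about blood reads. Of the others, 5 had a ratio under 0.5, such as IL7R (0.176) and TRAC (0.156). TCF7 (1.95) and KLRB1 (1.44), with 16 reads each over the scramble libraries, were higher. Lower erythroid transcription alone would leave other blood markers in place, whereas the median of 32 neutrophil, monocyte, T and NK cell markers was 0.413 (interval 0.326 to 0.926), 18 of them under 0.5. These intervals are too wide to decide, and they mix markers that the cells express with markers that they barely express. Blood RNA in scramble and lower transcription in the knockdown cells thus cannot be told apart for these genes.

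Hypoxia and glycolysis genes were lower in the knockdown groups. With their estimated correlation of 0.764, camera did not call the list (adjusted p = 0.443 in K2133 and 0.404 in K2231). The median log2 fold change of the list in K2231 was -0.86 (interval -1.25 to -0.74). Minus the median of all tested genes it was -0.87 (interval -1.28 to -0.75), which argues against a factor per library, since that would move all genes alike. With a trend on GC content and exon length removed it was -0.83 (interval -1.35 to -0.71) for 28 of 28 genes. That trend moved tested genes by -0.063 to 0.071 (5th to 95th percentile), which argues against GC content and length as the whole cause. A culture state such as oxygen or cell density that differs between cultures stays a candidate explanation: the list's median differed by 0.41 between scramble replicates 2 and 3, where random lists of the same size reached 0.12 at their 95th percentile, and the other scramble pairs differed by -0.13 and 0.27. In K2133 the median was -0.51 (interval -0.89 to -0.33). That is a difference between means of 3 libraries, which spread less than single libraries, so it cannot be set directly against the scramble pairs. An effect of the knockdown, or of infection if the scramble cells were not infected, stays open too, and with 3 libraries per group and no record of culture conditions used here these cannot be told apart.

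Several genes differed between K2133 and K2231 in opposite directions from scramble, with limma's test of the difference between the groups. ELANE differed by -2.75 (K2133 minus K2231, log2). PRTN3 differed by -1.94, its K2231 call against scramble being lost without scramble replicate 1 or 2 or K2231 replicate 2 or 3 (adjusted p = 0.0762 to 0.0978). GLB1 differed by -1.13, its K2231 call being lost without scramble replicate 1 or K2231 replicate 3 (adjusted p = 0.0503 to 0.0612). EI24 differed by -1.12. MILR1 differed by -1.10, its K2231 call being lost without scramble replicate 1 or 3, K2133 replicate 3 or K2231 replicate 2 or 3 (adjusted p = 0.0533 to 0.117). CCND2 differed by -0.44, its K2231 call being lost without scramble replicate 1 or 3, K2133 replicate 1 or 2 or K2231 replicate 1 (adjusted p = 0.0545 to 0.112). In all, 171 genes were called in opposite directions in the 2 knockdown groups. That number was 73 without scramble replicate 1, 112, 98 and 102 without K2133 replicate 1, 2 and 3, 103 without K2231 replicate 2, 82 with no filter on low values and 102 with fits to only the groups compared.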

How the results depend on the processing

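The counts from other splits of the libraries, the voom fit, median-ratio scaling, quantile normalization of the lists and the subtraction of the epithelial profile were chosen only after seeing the data. The total numbers of genes called stayed within 1.5 times under every alternative run except 1: with only 2 groups in the fit, both knockdowns against scramble called 2538 genes in place of 4738, a fit in which the difference between K2133 and K2231 adds to the residual spread. By direction, the higher genes in K2133 went from 1907 to 1197 without K2133 replicate 2, the lower ones between the knockdown groups from 1741 to 1134 without K2231 replicate 2, and those higher in both from 962 to 606 without K2133 replicate 2 and 604 with no filter. Quantile normalization turned the balance, with 2054 higher and 1955 lower in K2133, 2604 and 2434 in K2231, 2473 and 2352 in both against scramble and 1922 and 1989 between the knockdown groups. Leaving out each library in turn gave 2637 to 4051 genes for K2133 against scramble, 3573 to 5122 for K2231, 3348 to 4755 for both and 2560 to 4196 between the knockdown groups, 1439 to 2438 genes changed alike in both, and a correlation of fold changes of 0.583 to 0.663. Called lists numbered 7 to 10, 8 to 12, 7 to 9 and 6 to 8. With an estimated correlation camera called 0, 0, 0 and 0 lists (fry called 17, 16, 19 and 16), and with no filter 15 lists were called in K2231, 5 higher and 10 lower; the cause was not tested.

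With the epithelial profile subtracted, for which K2133 replicate 1 was also left out, 2949, 4589, 4158 and 2788 genes were called, of which 2793, 4484, 3992 and 2699 were the same genes. Leaving out that library alone gave 2921, 4590, 4143 and 2761, so most of the loss went with the library and not with the subtraction. AKR1B10 then stood at 0 in K2133 and 0 in K2231, S100A6 in K2133 at -0.62 and FN1 in K2133 at -0.0068, since the profile subtracted holds these genes. Quantile normalization turned MT-ATP6 in K2231 to 0 and MT-CO1 in K2231 to -0.016, both among the highest values, where it sets the same rank to 1 common value in all libraries. The voom fit on recovered reads called 4021, 4892, 4623 and 3944 genes, and median-ratio scaling 3986, 4965, 4793 and 3799. Of 540 calls of named genes in the contrasts, 522 were kept with quantile normalization, 484 with no filter, 539 with median-ratio scaling and 493 with the profile subtracted (499 without K2133 replicate 1 alone), and 485 to 505 when a knockdown library was left out. Without scramble replicate 1, 2 or 3, 484, 505 and 517 of 536 such calls were kept.

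The replicate numbers do not pair the libraries: the correlation of same-numbered libraries' deviations was -0.0442 to 0.0321 over 9 pairs, and 2 libraries correlated best with their own number in both other groups. With the replicate block, 3384, 4359, 4204 and 3208 genes and 7, 9, 7 and 6 lists were called, and 1827 genes changed alike in both.

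Of the 10 splits of 6 libraries into 3 and 3, 1 called as many genes as the real one in each comparison, with only the 2 groups in the fit. The real splits gave 3457 genes for K2133 against scramble, 3923 for K2231 and 4253 between the knockdown groups, and the highest other split 0 each by limma, with 480, 456 and 399 genes at an unadjusted p under 0.05 against 5318, 5723 and 5708. 10 splits cannot give a share under 0.05. For both knockdowns, 1 of 84 splits gave as many genes as the real 2538, so chance can be excluded for single libraries if the replicates are independent, which the labels do not say. The highest others, 2225 and 1116, set K2231 and K2133 apart from the rest, and the 3 groups alone are too few for a share under 0.05. The alternatives fixed beforehand with count-based normalization and tests were not run. The deposited values are FPKM, and of the tests on reads only limma-voom was run, on the genes with recovered reads. Depth limits low genes: genes with an FPKM of at least 1 in fewer than 3 libraries were not tested.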

Other observations

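The 7-mer regressions in this part were chosen before their results were seen, and the shares and numbers of genes with a 7-mer only after. The gene lists and limma's contrasts were fixed before the data were examined. Signalling and stress lists had members that moved without the list being called. Of all tested genes, 29.3% were called in K2133 and 36.3% in K2231, so called members alone do not set a list apart. Of 13 immediate early genes, 2 rose and 3 fell in K2133 (list adjusted p = 0.664, 2 and 3 adjusted over the list alone) and 0 rose and 5 fell in K2231 (list adjusted p = 0.114, 2 and 5 adjusted over the list alone), and the K2231 list passed without K2231 replicate 3 (adjusted p = 0.0383) or with no filter on low values (adjusted p = 0.0048). The AP-1 subunit gene JUN fell in both (-1.28 and -1.80), as did ZFP36 (-0.58 and -0.83), whose product promotes decay of cytokine mRNAs. Of 14 MAPK feedback genes, 3 rose and 2 fell in K2133 (list adjusted p = 0.664, 3 and 2 adjusted over the list alone) and 3 rose and 3 fell in K2231 (list adjusted p = 0.797, 5 and 3 adjusted over the list alone), and the ERK phosphatase gene DUSP6 was higher in both (0.99 and 0.69). Of 25 interferon response genes, 2 rose and 9 fell in K2133 (list adjusted p = 0.156, 2 and 9 adjusted over the list alone) and 5 rose and 8 fell in K2231 (list adjusted p = 0.797, 5 and 8 adjusted over the list alone), and the K2133 list passed as lower with no filter (adjusted p = 0.0428). IFI27 (-1.18 and -1.15) and BST2 (-0.41 and -0.50) were lower in both, while IFIT1 was lower in K2133 (-0.68) and differed between the knockdown groups by -0.77. Of 16 heat shock genes, 1 rose and 2 fell in K2133 (list adjusted p = 0.825, 1 and 1 adjusted over the list alone) and 4 rose and 1 fell in K2231 (list adjusted p = 0.258, 4 and 1 adjusted over the list alone), with HSPA1B (-0.83) lower in K2231 and HSPB1 (-0.35) lower in K2133.

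Of 12 adhesion and homing genes, 2 rose and 4 fell in K2133 (list adjusted p = 0.825, 4 and 4 adjusted over the list alone) and 1 rose and 4 fell in K2231 (list adjusted p = 0.143, 2 and 8 adjusted over the list alone), and the K2231 list passed as lower with no filter (adjusted p = 0.0318). The integrin gene ITGA4 rose in both and the selectin ligand gene SELPLG fell in both (-0.61 and -0.71). Of 17 heme and iron genes, 2 rose and 3 fell in K2133 (list adjusted p = 0.664, 2 and 3 adjusted over the list alone) and 4 rose and 5 fell in K2231 (list adjusted p = 0.838, 5 and 5 adjusted over the list alone), the ferritin light chain gene FTL being lower in both (-0.28 and -0.32). Of 20 genes of circular RNA biogenesis and turnover, 5 rose and 3 fell in K2133 (list adjusted p = 0.551, 5 and 3 adjusted over the list alone) and 8 rose and 2 fell in K2231 (list adjusted p = 0.142, 9 and 3 adjusted over the list alone). MBNL1, a splicing regulator, was lower in both (-0.24 and -0.41), and METTL3 was higher in both (0.29 and 0.44). Of 3 replication-dependent histone genes, 0 rose and 1 fell in K2133 (list adjusted p = 0.249, 0 and 1 adjusted over the list alone) and 0 rose and 0 fell in K2231 (list adjusted p = 0.97, 0 and 0 adjusted over the list alone). The median, mean and test of a list differed in sign for the MAPK and adhesion lists in K2133 and for the interferon and histone lists in K2231.

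A hypothesis was tested that genes lower in 1 knockdown group hold matches of a hairpin's guide seed in their 3' UTRs. Among 16279 7-mers in 10132 genes (72 further protein coding genes had no 3' UTR to search), AAAAGCT, in 2182 genes, had the strongest tie to lower values in K2133 than in K2231, with an effect of -0.062 on the log2 difference (Bonferroni-adjusted p = 1.26e-18), -0.048 against scramble in K2133 and 0.015 in K2231. GCTTCAC, in 1026 genes, had the strongest tie to lower values in K2231, with a K2133 minus K2231 effect of 0.077 (Bonferroni-adjusted p = 1.56e-17), -0.11 against scramble in K2231 and -0.035 in K2133. In all, 6 and 5 7-mers passed, of which 3 and 2 overlapped the first when shifted by 1 base. TCTTCAC, 1 of the 5, differed from GCTTCAC only in its first base. The p-values of this regression are 1-sided. Those of TAAAAGC (Bonferroni-adjusted p = 0.0356) and AAAGCTG (0.0459), both tied to lower values in K2133, would not pass if doubled for 2 sides. Among 145 genes called lower in K2133 than in K2231 by at least 0.5, 50 (34.5%) held AAAAGCT, against 2132 of 9987 others (21.3%), and among 339 genes lower in K2231, 63 (18.6%) held GCTTCAC, against 963 of 9793 (9.83%), without regard to UTR length. Both 7-mers were picked for this same difference in the same genes, so the higher shares follow from the choice and add no support. Of the 8 genes named as lower in K2133 only 2 (SLC28A3 and DEGS1) held AAAAGCT, and of the 8 named as lower in K2231 only 1 (TGM5) held GCTTCAC, so a match of these 7-mers does not account for most of the genes that differ most. Off-target activity of the guides on part of the other genes stays a candidate explanation, but the effects per gene are small, genes are not independent, and the hairpin sequences were not used here, so the match of these 7-mers to the guides was not tested.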
